A study of Drosophila melanogaster with 14 samples.

How the data were processed

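Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA bound by a protein, or carrying a histone mark, with an antibody, and regions where sequenced fragments pile up are called peaks. The study covered Drosophila melanogaster of the Iso1 strain, the strain of the reference genome, in whole embryos aged 8 to 16 hours and in wing imaginal discs, the larval tissue that forms the adult wing, dissected from wandering larvae. Of the 14 libraries, 9 came from embryos (3 of GAF, 3 of Yki, 2 of H3K4me3 and 1 of input chromatin) and 5 from wing discs (2 of GAF, 1 of Yki and 2 of input). Per the labels' protocols, libraries were made by transposase tagmentation and 12 cycles of PCR, size-selected near 225 bp and sequenced on an Illumina HiSeq instrument. Such a protocol amplifies fragments before counting, and tagmentation has sequence preferences of its own that input libraries share.

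The values analysed were 5 deposited peak lists, 1 per antibody and tissue. Per the submitters' processing notes, base calls came from CASAVA 1.7.0, the aligners named were BWA and Bowtie, and positions are on the dm3 build (release 5 of the genome). Names in both wing disc lists begin with MACS, a peak caller, whereas the embryo lists hold positions without names, so the caller of the embryo lists, all calling thresholds, the way replicates were combined and the use of the input libraries are not given in the sources used here. Both wing disc lists also carry a score per peak, which is the authors' own, of a scale not given in the sources used here, and which served only to rank peaks within its list. Positions were the authors' peak starts and ends, counted from 0 in the deposited lists and from 1 in the text. Since there is 1 list per antibody and tissue, agreement between replicates could not be measured, and sequencing depth is unknown. List length and peak width move with depth and calling threshold, so lists of different length or width are not evidence of more or less binding. The tissues may have been called in different ways, which the files cannot separate from a difference between tissues.

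Overlaps were counted with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A peak of the first list counted as overlapping when it shared at least 1 bp with any peak of the second. The expected number came from 10000 circular shifts, in which all peaks of the first list on a chromosome arm moved by the same random distance within the span covered by the 5 lists, which keeps widths and spacing. Enrichment is the observed number over the mean of the shifts, and its range uses the central 95% of the shifts. The two-sided p was adjusted by the Benjamini-Hochberg method over the 10 overlaps, and the smallest p the shifts can give is 0.0002. Circular shifts do not keep the tendency of peaks to lie near genes. Local shifts of 5 to 50 kb, with each peak moved separately, were run as an alternative. They keep the wider region but also move a peak off its promoter, so neither kind of shift removes a shared preference for promoters. Shares carry Wilson 95% intervals, differences of shares Newcombe intervals and odds ratios Wald intervals. Contrasts between classes of peaks used Fisher's exact test, two-sided, adjusted over 12 contrasts, and Mantel-Haenszel odds ratios over quartiles of peak width used statsmodels 0.14.6. Medians of score or width were compared by a two-sided permutation test with 100000 resamples, for which 1e-05 is the smallest p. Peaks are not replicates: p-values and intervals describe these lists and cover counting error only. Comparisons of 1 list with another also treat the lists as independent, although many sites are shared between them. Merged sites are the unions of touching peaks over the 4 lists of Yki and GAF, and their expected numbers came from 1000 shifts.

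The overlap step was tested on simulated lists with the peak widths of the Yki and GAF embryo lists at random positions. With 0, 10, 30 and 60% of peaks planted on the other list it recovered 0.375, 10.5, 30.0 and 59.6%, and it called 10 of 200 independent pairs. The simulated lists lack the clustering of the real peaks, so the rate of false calls for clustered lists was not measured. The tests, the other settings to be tried and the rule for named regions were fixed before the data were examined. That rule took the 5 peaks per tissue in both the Yki and the GAF list with the highest score (in embryos, which have none, the greatest width) and the 5 regions of 100 kb with most peaks in each list. The other settings were a reciprocal overlap of 50%, midpoints within 500 bp, local shifts, the 50% of each list with the highest score or width, lists drawn to the 3749 peaks of the shortest list (20 draws), and removal of chromosomes X and 4 with heterochromatin scaffolds. Contrasts other than the 2 planned ones on Yki embryo peaks, the comparison of Yki with GAF at H3K4me3, merged sites and score quartiles were added after the data were seen. The planned tests on gene lists, position relative to genes and motif frequency were not run, because the only gene table used here belongs to release 6 and coordinates were not converted. No gene is therefore named by position.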

Results

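Yorkie (Yki) is the transcriptional coactivator of the Hippo pathway, which restrains organ growth, and reaches DNA through partner proteins such as Scalloped. GAGA factor (GAF), encoded by Trithorax-like, binds GA-rich DNA and helps keep promoters open. Trimethylation of histone H3 at lysine 4 (H3K4me3) marks active promoters. The study mapped Yki and GAF in embryos of 8 to 16 hours and in wing imaginal discs, and H3K4me3 in embryos, which allows the sites of both proteins to be compared with each other, between tissues and with H3K4me3 peaks. In embryos the peak lists held 3749 Yki peaks, 6470 GAF peaks and 6499 H3K4me3 peaks. In wing discs they held 6491 Yki peaks and 6328 GAF peaks. Median peak width was 438 bp for Yki and 583 bp for GAF in embryos, 418 bp and 634.5 bp in wing discs, and 1262 bp for H3K4me3. The lists covered 2.11 Mb (Yki embryo), 6.16 Mb (GAF embryo), 10.8 Mb (H3K4me3), 3.53 Mb (Yki wing disc) and 6.14 Mb (GAF wing disc). There was 1 list per antibody and tissue, so there are no replicate values, and for Yki in wing discs the labels name 1 library. Depth is unknown.

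Most Yki peaks lay on GAF peaks in both tissues. In embryos, 2580 of 3749 Yki peaks (68.8%, 95% Wilson interval 67.3 to 70.3) overlapped a GAF peak, where circular shifts gave 283 on average (7.55%). This is an enrichment of 9.11 (range over shifts 8.01 to 10.4). In wing discs, 4089 of 6491 Yki peaks (63.0%, 61.8 to 64.2) overlapped a GAF peak, an enrichment of 8.27 (7.45 to 9.23) over the 495 given by shifts. GAF peaks carried Yki less often: 32.7% (31.6 to 33.9) of GAF peaks in embryos and 51.8% (50.6 to 53.1) in wing discs overlapped a Yki peak. These shares also move with list length and peak width. In embryos 3749 Yki peaks stood against 6470 GAF peaks, and in wing discs the 4089 Yki peaks with GAF met 3281 GAF peaks. For the overlaps of Yki with GAF in both tissues and the other 8 tested, the adjusted two-sided p was 0.0002, the smallest the shifts can give.

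**Figure D1:**
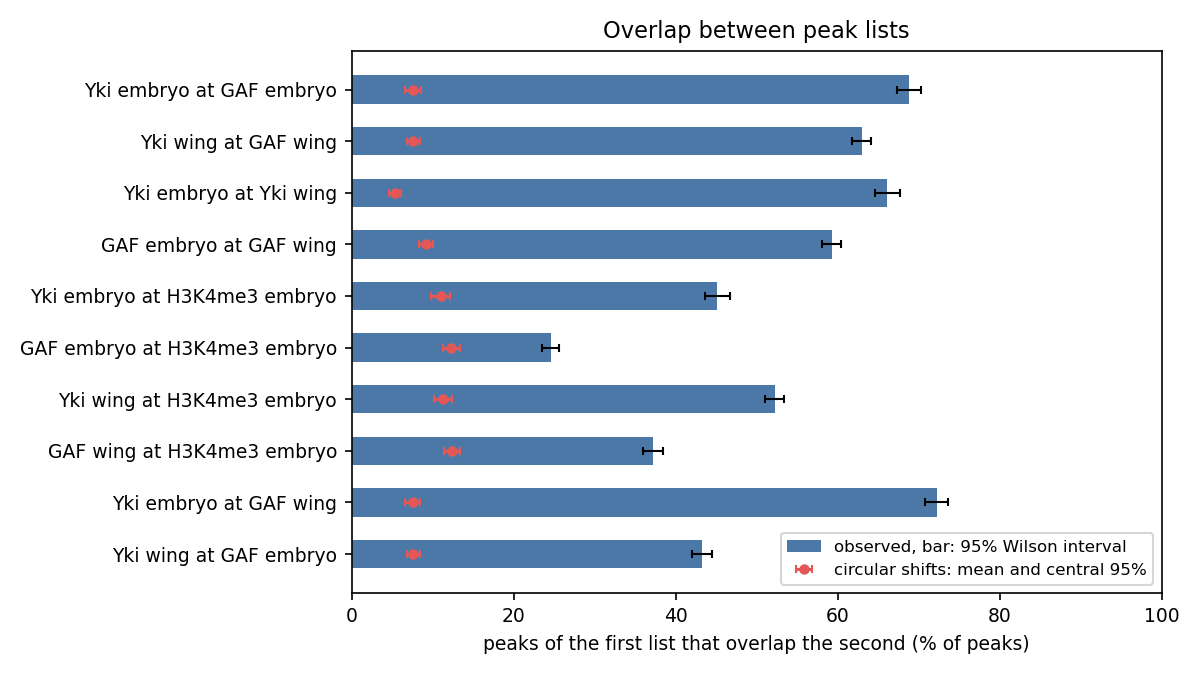
Share of peaks of the first list (%) that overlapped the second by at least 1 bp, for 10 pairs of lists. Bars are observed shares with 95% Wilson intervals and red points are the mean of 10000 circular shifts with their central 95%; every bar lies beyond its shifts, from 24.6% (GAF at H3K4me3 in embryos) to 72.2% (Yki in embryos at GAF in wing discs).

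The share of Yki peaks with GAF was lower in wing discs than in embryos (difference -5.82 percentage points, 95% interval -7.70 to -3.92; Fisher's exact test, two-sided, p = 2.46e-09). The ratio of the enrichments over shifts, wing disc over embryo, was 0.907. Its range of 0.767 to 1.07 is the spread of single shifts and not the error of the ratio. It therefore does not test whether the enrichments differ. The size and direction of the difference in share depended on the settings. It was -17.8 points among the 50% of each list with the highest score or, in embryos, width, -16.1 points among the widest 50% of each list, and -1.97 points (median p of Fisher's exact test 0.0818) with lists drawn to equal length. Such draws remove GAF peaks at random, which lowered the shares to 40.0% in embryos and 38.1% in wing discs and by itself shrinks their difference. The difference was 4.84 points in the other direction with a reciprocal overlap of 50% (20.3% in wing discs and 15.4% in embryos), and -0.861 points (Fisher's exact p = 0.412) with midpoints within 500 bp.

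Both proteins shared many sites between the tissues. Of the Yki embryo peaks, 2480 (66.2%, 64.6 to 67.6) overlapped a Yki wing disc peak, with an enrichment of 12.3 (10.7 to 14.3). In the other direction 38.7% of Yki wing disc peaks overlapped a Yki embryo peak. Of the GAF embryo peaks, 3833 (59.2%, 58.0 to 60.4) overlapped a GAF wing disc peak, with an enrichment of 6.45 (5.89 to 7.09), and 61.1% of GAF wing disc peaks overlapped a GAF embryo peak. Overlap across both protein and tissue was uneven. Yki embryo peaks overlapped GAF wing disc peaks in 72.2% of cases (70.7 to 73.6; enrichment 9.58), whereas 43.2% (42.0 to 44.4) of Yki wing disc peaks overlapped a GAF embryo peak (enrichment 5.66).

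Yki embryo peaks with GAF were found in wing discs more often than those without, a difference not detected within quartiles of peak width. Of the 2580 Yki embryo peaks that overlapped a GAF embryo peak, 69.7% (67.9 to 71.5) were also in the Yki wing disc list, against 58.3% (55.4 to 61.1) of the 1169 without GAF. The odds ratio was 1.65 (1.43 to 1.91; Fisher's exact test, two-sided, p = 1.08e-11, adjusted over 12 contrasts 1.30e-11). Over quartiles of Yki peak width, a test chosen after the data were seen, the odds ratio was 1.04 (0.894 to 1.22). Without that correction it was 3.18 with a reciprocal overlap of 50% and 1.19 (Fisher's exact p = 0.0119) with midpoints within 500 bp.

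Merging touching Yki and GAF peaks gave 11285 sites. In 1525 of them all 4 lists were present, where shifting every list gave 7.92 on average and at most 21 in 1000 shifts. Sites with GAF in embryos alone numbered 2423, Yki in wing discs alone 1975, GAF in wing discs alone 1309, GAF in both tissues without Yki 1045, and Yki in embryos alone 432. Yki in wing discs was present at 1.26% (0.895 to 1.76) of the 2629 sites with GAF in embryos but not in wing discs, at 43.7% (41.7 to 45.7) of the 2380 sites with GAF in wing discs but not in embryos, and at 59.3% (57.6 to 60.9) of the 3529 sites with GAF in both. Yki in embryos was present at 6.96% (6.05 to 8.00), 11.1% (9.93 to 12.5) and 54.3% (52.7 to 56.0) of the same 3 classes. Merging favours wide sites: the median width was 2025 bp for sites in all 4 lists and 371 bp for sites with GAF in embryos alone.

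**Figure D2:**
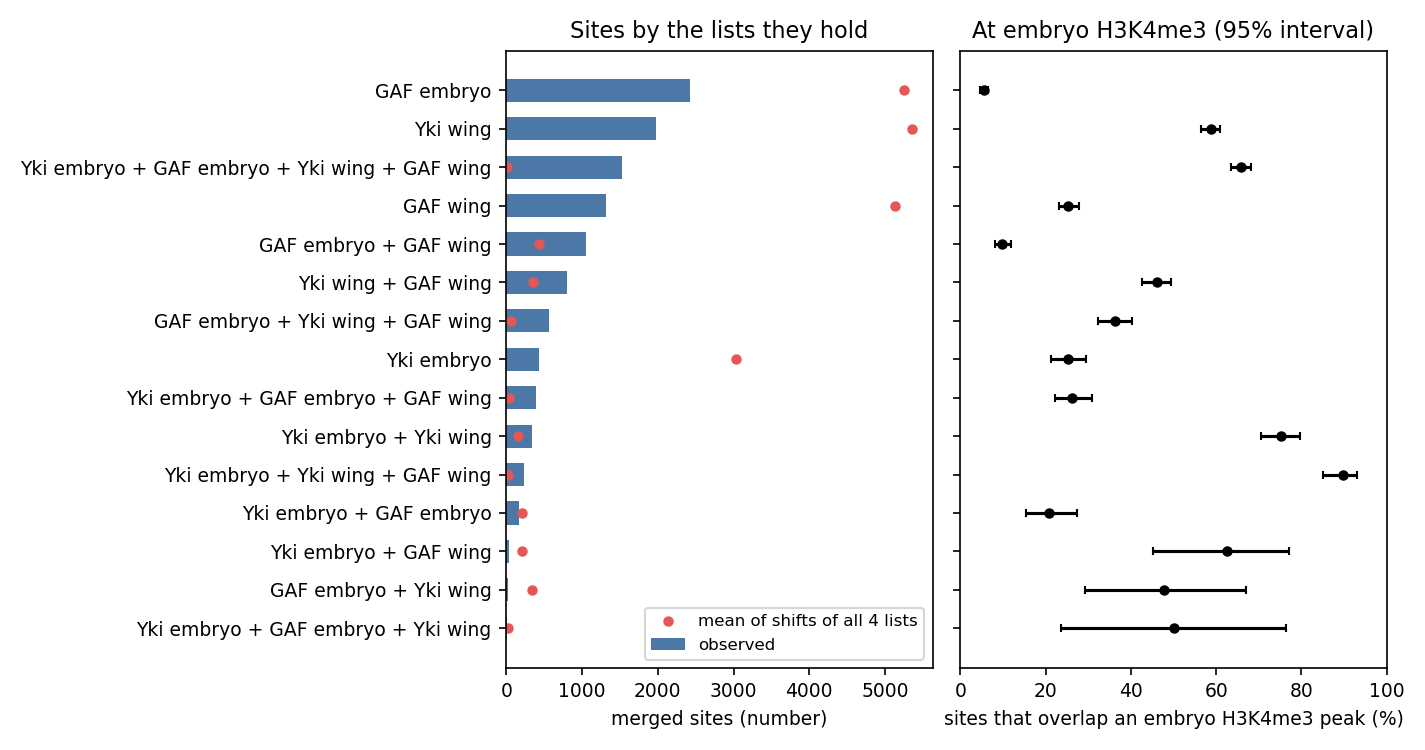
Merged sites by the lists they hold (left, number of sites; red points, mean of 1000 shifts of all 4 lists) and the share of each class that overlapped an embryo H3K4me3 peak (right, %, with 95% Wilson intervals). Sites in all 4 lists numbered 1525 against 7.92 in the shifts; the H3K4me3 share ran from 5.49% for GAF in embryos alone to 89.7% for Yki in both tissues with GAF in wing discs.

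Peaks of both proteins overlapped embryo H3K4me3 peaks, Yki peaks more often than GAF peaks under 3 of 4 overlap definitions. In embryos, 45.2% (43.6 to 46.8) of Yki peaks overlapped an H3K4me3 peak, an enrichment of 4.11 (3.70 to 4.59), and so did 24.6% (23.5 to 25.6) of GAF peaks, an enrichment of 1.99 (1.83 to 2.19). Of the wing disc peaks, 52.2% (51.0 to 53.4) of Yki and 37.2% (36.0 to 38.4) of GAF overlapped the embryo H3K4me3 list, with enrichments of 4.64 (4.23 to 5.12) and 3.01 (2.78 to 3.27). The odds ratio of Yki against GAF was 2.53 (2.32 to 2.76) in embryos and 1.85 (1.72 to 1.98) in wing discs (Fisher's exact test, two-sided, p = 8.07e-101 and 7.80e-66). These p-values and intervals treat the Yki and GAF lists as independent. Yet 2580 of 3749 Yki embryo peaks and 4089 of 6491 Yki wing disc peaks lay on GAF peaks, so many sites count on both sides. The odds ratio was 1.91 and 1.64 with midpoints within 500 bp, and 2.47 and 2.41 with peak midpoints inside H3K4me3. With a reciprocal overlap of 50% no such difference was detected: 6.03% of Yki and 5.64% of GAF peaks in embryos (1.07, 0.904 to 1.27), and 7.15% and 7.55% in wing discs (0.942, 0.825 to 1.08). That definition leaves out peaks less than 50% as wide as the H3K4me3 peak, and Yki peaks were the narrower by median. H3K4me3 in wing discs was not analysed here, so these values compare wing disc binding with embryo H3K4me3 peaks, whose position relative to genes was not analysed. Among merged sites, H3K4me3 overlapped 65.8% (63.4 to 68.2) of those in all 4 lists and 89.7% (85.1 to 93.0) of those with Yki in both tissues and GAF in wing discs. It overlapped 58.7% (56.5 to 60.9) of sites with Yki in wing discs alone, 25.4% (23.1 to 27.8) of those with GAF in wing discs alone, and 5.49% (4.65 to 6.47) of those with GAF in embryos alone.

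Whether Yki peaks with GAF were marked by H3K4me3 more or less often than those without depended on how overlap was counted. With at least 1 bp shared, 40.3% (38.4 to 42.2) of Yki embryo peaks with GAF overlapped H3K4me3, against 55.9% (53.0 to 58.7) of those without. The difference was -15.5 points (-18.9 to -12.1) and the odds ratio 0.534 (0.464 to 0.614; Fisher's exact test, two-sided, p = 9.29e-19, adjusted 1.39e-18). With midpoints within 500 bp for both overlaps the odds ratio was 1.26 (1.07 to 1.48, Fisher's exact p = 0.00534), and with a reciprocal overlap of 50% it was 7.13 (5.40 to 9.42, p = 3.48e-40). The direction at 1 bp held with Yki midpoints inside H3K4me3 (0.653, 0.562 to 0.758), with midpoints within 500 bp for GAF alone (0.648, 0.569 to 0.737), and in the widest 50% of each list (0.280). It reversed with midpoints within 500 bp for H3K4me3 alone (1.41), and with a reciprocal overlap for GAF alone (2.69) or for H3K4me3 alone (4.99). Over quartiles of Yki peak width the first 3 odds ratios were 0.346 (0.295 to 0.405) at 1 bp, 1.19 (1.01 to 1.40) with midpoints within 500 bp and 2.94 (2.18 to 3.95) with the reciprocal overlap. With the GAF wing disc list in place of the embryo list, chosen after the data were seen, it was 1.29 (1.12 to 1.49, Fisher's exact p = 0.000501). In wing discs, at 1 bp, 47.3% (45.8 to 48.8) of Yki peaks with GAF overlapped embryo H3K4me3, against 60.6% (58.6 to 62.5) of those without (odds ratio 0.584, 0.527 to 0.647, Fisher's exact test, adjusted p = 6.41e-25).

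Peaks with both proteins had higher scores in wing discs, and were wider in embryos, than peaks with 1 of them. In embryos, where the lists hold no score, Yki peaks with GAF had a median width of 512 bp (quartiles 340 and 774) and those without 326 bp (256 and 465). GAF peaks with Yki had a median width of 1385.5 bp (932.5 and 2224), against 429 bp (306 and 620) without. Wider peaks overlap other peaks more readily, which this comparison does not remove. In wing discs, the authors' score had a median of 15.97 for Yki peaks with GAF (quartiles 11.3 and 23.54) and 11.3 (9.36 and 14.86) without. For GAF peaks it was 114.9 with Yki (25.22 and 299.98) and 18.87 (11.73 and 39.99) without. Each permutation p was 1e-05, the smallest 100000 resamples can give, and each difference had the same sign with midpoints within 500 bp. Along quartiles of the score, the share of GAF wing disc peaks with a GAF embryo peak rose from 30.8% (28.6 to 33.1) to 99.5% (99.0 to 99.7), and the share with a Yki wing disc peak from 27.6% (25.5 to 29.8) to 90.9% (89.4 to 92.2). For Yki wing disc peaks, the share in the Yki embryo list rose from 15.5% (13.8 to 17.3) to 73.4% (71.2 to 75.5), while the share at H3K4me3 went from 48.0% (45.6 to 50.4) to 57.2% (54.7 to 59.6). Neither the wing disc score contrasts nor these trends were corrected for peak width.

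**Figure D3:**
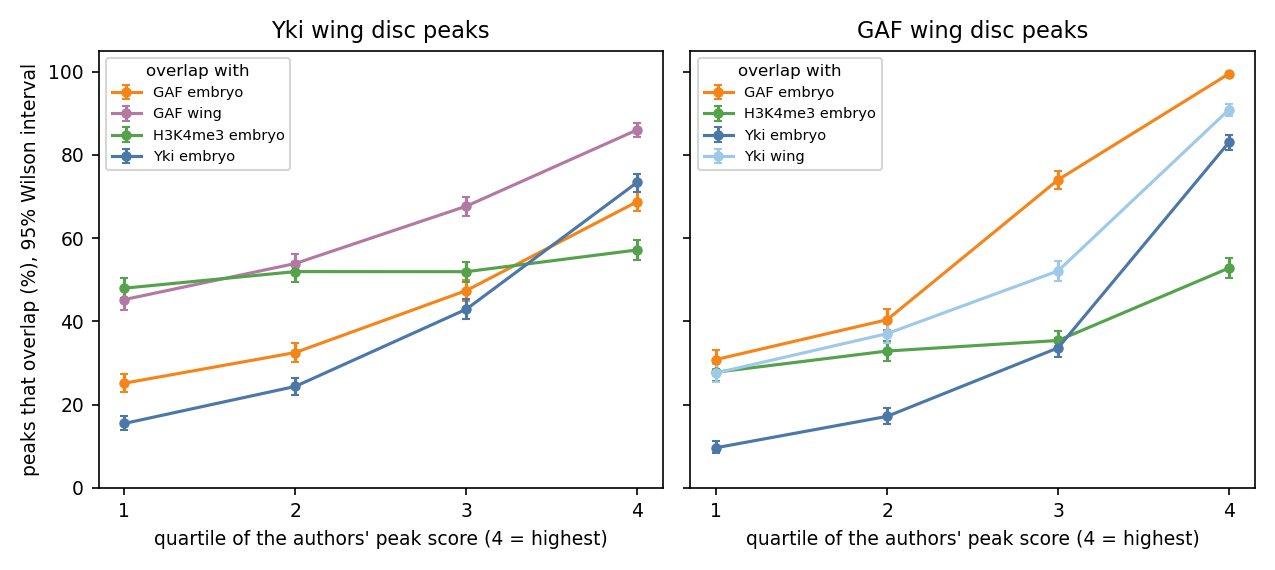
Share of wing disc peaks (%, with 95% Wilson intervals) that overlapped each other list, by quartile of the authors' peak score, for Yki (left) and GAF (right). The highest GAF quartile overlapped GAF embryo peaks in 99.5% of cases, and the Yki share at H3K4me3 moved least, from 48.0 to 57.2%.

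Across chromosome arms, the X chromosome held 20.3% (19.0 to 21.7) of Yki and 19.8% (18.8 to 20.8) of GAF embryo peaks, an odds ratio of 1.03 (0.933 to 1.14; Fisher's exact test, two-sided, p = 0.531). In wing discs it held 16.1% (15.2 to 17.0) of Yki and 20.04% (19.1 to 21.1) of GAF peaks, an odds ratio of 0.766 (0.699 to 0.839; Fisher's exact p = 8.38e-09, adjusted over 4 tests 3.35e-08). H3K4me3 peaks lay on X in 18.1% of cases (17.2 to 19.1). Unplaced scaffolds (U and Uextra) held 71 Yki embryo peaks, 34 GAF embryo peaks, 45 GAF wing disc peaks and 2 Yki wing disc peaks.

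The 5 widest Yki embryo peaks with GAF lay on dm3 at 3L 14747923 to 14753638 (5716 bp), 2R 4552899 to 4557159 (4261 bp), 2R 8474141 to 8477934 (3794 bp), 2L 2752428 to 2756113 (3686 bp) and 3R 7584149 to 7587802 (3654 bp). All 5 also overlapped Yki and GAF wing disc peaks, and all but the 3R peak overlapped H3K4me3. In wing discs, the 5 Yki peaks with GAF and the highest scores were at 3L 15129423 to 15130408 (score 115.33), 3L 3248339 to 3249563 (103.06), 2R 15993663 to 15994358 (100.66), 3L 17992397 to 17993236 (96.68) and 3L 16581234 to 16581980 (96.45). All but the peak at 3L 3248339 overlapped a Yki embryo peak. The GAF peaks under them ranged widely in score, from 11.16 at 3L 15129423 to 848.86 at 2R 15993663. What these regions contain in terms of genes was not analysed here.

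The regions densest in Yki and GAF peaks were partly shared between tissues. The region from 17400001 to 17500000 on 3R held 16 Yki and 32 GAF peaks in embryos, 23 Yki and 29 GAF peaks in wing discs, and 6 H3K4me3 peaks. The region from 9800001 to 9900000 on 2R held 15 and 25 in embryos, 25 and 21 in wing discs, and 19 H3K4me3 peaks, and both regions were among the 5 densest of at least 3 lists. Over 1205 such regions, the median was 3 Yki and 4 GAF peaks in embryos, 5 Yki and 4 GAF peaks in wing discs, and 4 H3K4me3 peaks. The region with most GAF embryo peaks, from 18000001 to 18100000 on 3L, held 37 of them with 7 Yki embryo peaks, 19 GAF wing disc peaks and 2 H3K4me3 peaks. The region with most Yki wing disc peaks, from 6400001 to 6500000 on 2R, held 29. H3K4me3 was densest elsewhere, with 35 peaks from 10300001 to 10400000 on 2L, where 3 Yki and 3 GAF embryo peaks lay. In the Yki embryo list the densest region was the first 100 kb of the unplaced scaffold Uextra, with 19 Yki embryo peaks and 0 in each other list.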

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

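The tests of the change between tissues in X share and in H3K4me3 overlap, and those of X copies and of peaks without GAF as part or whole of the cause, were chosen after the results were seen. The share of Yki peaks with GAF differed between tissues by -5.82 percentage points, wing disc minus embryo (95% interval -7.70 to -3.92), a difference that turned with the overlap required. Overlap with embryo H3K4me3 also differed in how it moved between tissues: the GAF share rose by 12.6 points from the embryo to the wing disc list and the Yki share by 7.05 points, a ratio of odds ratios of 1.37 (1.23 to 1.53, with the lists treated as independent). With peak midpoints counted inside H3K4me3 this difference was gone and the order in points turned: GAF rose by 9.66 points and Yki by 14.2, a ratio of 1.02 (0.903 to 1.16).

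The Yki wing disc list held a smaller X share than the Yki embryo list (odds ratio 0.752, 0.677 to 0.835), and this change differed from that of the GAF lists, with a ratio of odds ratios of 0.741 (0.646 to 0.849, with the lists treated as independent). The scores argue against weak peaks near the calling threshold: among the 50% of Yki wing disc peaks with the highest scores 14.8% (13.6 to 16.1) lay on X, still below the 20.3% of Yki embryo peaks. Fewer X copies in wing disc chromatin would lower GAF as well if both lists were equally sensitive to them. The GAF odds ratio of wing disc against embryo was 1.02 (0.930 to 1.11). Peak counts do not show whether the lists were equally sensitive, so fewer X copies cannot be excluded. In wing discs, 13.1% of Yki peaks without GAF lay on X against 17.8% of those with GAF (odds ratio 1.44, 1.25 to 1.67). In embryos, 21.3% of Yki peaks with GAF lay on X, against 20.3% of all Yki peaks, so those without GAF were less often on X there too. The contrast within wing discs is thus not particular to them, and its size in embryos was not tested. It cannot tell whether peaks without GAF are part of the cause. They are not the whole of it, since Yki peaks with GAF were also less often on X in wing discs than in embryos (0.803, 0.709 to 0.909). A difference between the tissues, the calling of peaks and the single library behind the Yki wing disc list stay open and untested.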

How the results depend on the processing

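Removal of unplaced and heterochromatin scaffolds alone, the GAF wing disc list in place of the embryo list, width quartiles, the widest 50% in both tissues, the restriction to GAF peaks in both tissues, mixed overlap definitions and all settings on Yki against GAF at H3K4me3 were chosen after the results were seen. All 10 overlaps stayed above their shifts with p past the threshold in 60 tests with settings fixed beforehand and 10 added ones. Local shifts gave the lowest enrichments, such as 6.31 for Yki at GAF in embryos, 5.78 in wing discs and 1.66 for GAF at H3K4me3 in embryos. Of 16 other tests fixed beforehand, 11 kept direction and side of the threshold. The tissue difference in the Yki share with GAF was 4.84 points, reversed, with a reciprocal overlap of 50%, lost its call at -0.861 points with midpoints within 500 bp and at -1.97 points (median p 0.0818) with lists drawn to equal length, and was -17.8 points in the upper 50% of each list, taken by width in embryos and by score in wing discs, against -16.1 (-18.6 to -13.6) by width in both. Draws to equal length remove GAF peaks at random, which by itself lowers both shares and shrinks their difference. The cause of the other changes was not tested. Yki embryo peaks kept in wing discs, with against without GAF, lost their call over width quartiles (1.04, 0.894 to 1.22). At H3K4me3, with a reciprocal overlap, the odds ratio of Yki against GAF lost its call in embryos (1.07) and turned, short of the threshold, in wing discs (0.942). The change between tissues of GAF over Yki lost its call with a reciprocal overlap (1.14) and with midpoints inside H3K4me3 (1.02). The H3K4me3 odds ratio of Yki embryo peaks with against without GAF reversed to 7.13 with a reciprocal overlap, 1.26 with midpoints within 500 bp and 1.29 with the GAF wing disc list. It kept its direction at 0.280 in the upper 50% of each list and with embryo-only GAF peaks left out (0.586). Over width quartiles it was 0.346, but they had to lower it and are no separate test. Among mixed definitions the odds ratio kept its direction with midpoints for GAF alone (0.648) and with Yki midpoints inside H3K4me3 (0.653), but reversed in others. The midpoint reversal came with the H3K4me3 criterion: with midpoints for GAF alone the odds ratio was 0.648, and with midpoints for H3K4me3 alone 1.41 (1.18 to 1.69), which over width quartiles was 1.16 (0.956 to 1.40), with 1 inside its interval. A reciprocal overlap reversed it for GAF alone (2.69, 2.24 to 3.24) and for H3K4me3 alone (4.99, 3.13 to 7.93), and for both it was 2.94 (2.18 to 3.95) over width quartiles. The cause of the reversal with the GAF wing disc list was not tested. The settings meant for tests of gene lists, of wing-disc-only against embryo-only genes, of position relative to genes and motif frequency were not run, for want of an annotation and sequence of the build of the peaks. No paired analysis was possible because the deposited lists are 1 per antibody and tissue and carry no replicate, and for the same reason no replicate could be left out. Depth is unknown, so a site absent from a list is not shown to be unbound.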

Other observations

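The contrasts of GAF peaks and of shared against unshared peaks, and the tests of width, genome position, weak peaks, chromatin and GAF peaks called in embryos alone, were chosen after the results were seen. GAF peaks with Yki overlapped H3K4me3 more often than GAF peaks without. In embryos, 52.3% (50.2 to 54.4) of GAF peaks with Yki overlapped H3K4me3, against 11.1% (10.2 to 12.0) of those without (odds ratio 8.83, 7.77 to 10.03). In wing discs the shares were 54.5% (52.8 to 56.2) and 18.5% (17.2 to 19.96), an odds ratio of 5.26 (4.69 to 5.90). GAF embryo peaks with Yki were also found in the GAF wing disc list in 91.3% of cases (90.0 to 92.4), against 43.7% (42.2 to 45.1) of those without. GAF peaks with Yki are wider, and these contrasts were not corrected for width.

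Sites held in both tissues were marked more often than sites of embryos alone. Of GAF embryo peaks also in the wing disc list, 36.7% (35.2 to 38.2) overlapped H3K4me3, against 6.90% (5.996 to 7.93) of the others, with an odds ratio over width quartiles of 4.60 (3.85 to 5.49). For Yki embryo peaks the shares were 57.5% (55.5 to 59.4) and 21.0% (18.9 to 23.4), with an odds ratio over width quartiles of 4.45 (3.78 to 5.25). The GAF wing disc list went another way: GAF wing disc peaks shared with embryos overlapped embryo H3K4me3 in 36.6% of cases and the others in 38.1% (Fisher's exact p = 0.240), and over width quartiles the odds ratio was 0.416 (0.364 to 0.475). Yki wing disc peaks shared with embryos overlapped H3K4me3 in 58.1% (56.2 to 60.0) of cases and the others in 48.5% (46.9 to 50.05), an odds ratio of 1.47 (1.33 to 1.63). It was 1.21 (1.09 to 1.35) over width quartiles. When peak midpoints inside H3K4me3 were counted, the shares were 42.0% and 42.4%, and the odds ratio over width quartiles was 0.919 (0.824 to 1.02). Of Yki wing disc peaks with GAF, 51.9% (50.3 to 53.4) were also in the Yki embryo list, against 16.4% (14.98 to 17.9) of those without, a contrast not corrected for width.

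Yki and GAF peaks coincided in both tissues, and 3 technical explanations were weighed. For an artifact fixed to genome positions, GAF sites of 1 tissue alone were compared. Yki wing disc peaks were 34.8 times (24.7 to 49.0) as frequent at GAF sites of wing discs alone as at those of embryos alone. The matching ratio for Yki embryo peaks was 0.625 (0.522 to 0.748), lower at sites of their own tissue. An artifact present in all libraries would lie among the 3529 sites with GAF in both tissues, which neither ratio covers. This explanation therefore stays open in both tissues. Weak peaks near the calling threshold would lower the enrichment among the highest scores, which instead was 10.5 in wing discs. Chromatin that enriches in any immunoprecipitation of a tissue may still contribute, since the test on H3K4me3 gave -15.5 points (-18.9 to -12.1) at 1 bp and -8.86 (-12.1 to -5.69) with Yki midpoints inside H3K4me3, but the opposite sign with a reciprocal overlap or midpoints within 500 bp, and recruitment of both proteins to the same sites was not tested by this design.

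At 1 bp, Yki embryo peaks with GAF overlapped H3K4me3 less often than those without. Yki peak width works against this difference. Yki peaks with GAF were wider, and H3K4me3 overlap was higher in the widest quartile than in the narrowest, with GAF (61.0 against 24.1%) and without (76.8 against 53.0%). Width quartiles therefore had to lower the odds ratio, which became 0.346 (0.295 to 0.405), so they are no separate test. The widths of GAF and H3K4me3 peaks were not tested as a cause. GAF peaks called in embryos alone were marked least, but leaving them out gave 0.586 (0.509 to 0.675). The dependence on the overlap definition stays open, and GAF peaks that flank H3K4me3 peaks without sharing their centres were not tested as a biological explanation.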
